A study of Mus musculus with 97 samples.

How the data were processed

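The values are RPKM (reads per kilobase of gene per M reads, where M stands for mega), computed by the authors and deposited as 1 table with a column per library. The submitters' notes name bcl2fastq, TopHat2 2.1.0, HTSeq 0.6.0 and DESeq2, and the mm9 genome build, without stating the order of the steps or the gene lengths used. No between-library factor beyond sequencing depth was found in the values. Of 37991 genes, 181 had no value in any library, which left 37810. Of these, 4949 were 0 in every library. In 32848 of the 32861 genes above 0, all values were whole multiples of 1 read's worth after each library's depth was divided out, within a tolerance of 0.0001. Read totals per library were recovered from these multiples and served for depth and for 1 alternative test. Matching to the current mouse gene table succeeded for 32908 Ensembl identifiers, 5927 of which now carry another symbol. The symbols and identifiers printed here are those of the deposited table.

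Columns were matched to samples through the library names in the sample labels. Titles number the libraries of a group 1 and 2, and library names carry a further number that recurs in both regions. The labels do not say whether libraries that share a number came from 1 animal, so p-values measure only the spread between these samples. Whole libraries, not reads, were the unit of every test.

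Values were analysed as log2(RPKM + 1), without further normalization. Changes on this scale understate the fold change of genes with low values. Genes with at least 1 RPKM in at least 2 of the libraries of a fit were tested, 16090 genes in the 24 TRAP libraries and 14186 in the 8 libraries that compared TRAP with tissue RNA. Linear models were fitted with limma 3.58.1 (empirical Bayes with an intensity trend), with 1 mean for each combination of region, age and genotype. This left 12 residual degrees of freedom in the fit of 24 libraries and 4 in the fit of 8. Region and genotype comparisons are averages over the 3 ages. Each was tested two-sided with Benjamini-Hochberg adjustment over all genes tested, at an adjusted p under 0.05. The change of the Eed effect with age was tested with limma's F-test. Errors of log2 changes are standard errors from the fit, and errors of RPKM are standard deviations between libraries.

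Gene lists were tested with limma's camera at its preset correlation between genes of 0.01, two-sided and adjusted over the lists of 1 comparison. Each test was repeated with a correlation estimated from the data, and member counts were also adjusted over the list alone. The 24 lists were microglia homeostatic, clearance receptors and opsonins, lysosome, disease-associated microglia, MHC class II, MHC class I, interferon response, inflammatory cytokines, Polycomb subunits and H3K27 demethylases, developmental transcription factors, cell cycle inhibitors, proliferation, border macrophages, monocytes neutrophils and lymphocytes, neurons, striatal neurons, cerebellar neurons, astrocytes, oligodendrocytes, endothelial cells, mural cells and fibroblasts, choroid plexus, immediate early and heat shock, and sex-linked. Some genes stand in more than 1 list, such as Axl, Clec7a, Cd63, Ctsb and Otx2.

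Named genes follow a rule. For the region difference in controls and the Eed effect in each region, the 10 largest rises and the 10 largest falls were taken among genes that passed the test. They also had to have the same sign at all 3 ages and a mean of at least 2 RPKM in the higher group. For the other comparisons, the limit was 5 in each direction. Symbols of predicted genes (Gm and a number, or ending in Rik), those that start with Mir, Snor, Rpl, Rps or LOC, clone names and sex-linked genes are left out of this ranking. From each list, up to 4 members with the smallest adjusted p are named, and Eed, Ezh2, Suz12 and Cx3cr1 always. The comparisons, lists, tests and this rule were fixed before the data were examined. The restriction to TRAP-enriched genes, the difference in enrichment between regions, the carry-over score and its tests were chosen after the data were seen.

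A carry-over score was computed for each library as the mean log2(RPKM + 1) of the neuron list minus that of the homeostatic list. Scores were compared between groups of 6 libraries with two-sided exact permutation tests over 924 assignments, adjusted over 16 tests. TRAP-enriched genes were those higher in TRAP than in tissue RNA in both regions, at an adjusted p under 0.05 and a log2 change of at least 1. For comparisons among them, every library was rescaled to the median of these genes.

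Before any comparison was read, values were simulated from the measured means of each region and age, with independent normal noise of each gene's spread. In each region, 200 genes were changed. At a log2 change of 1, the fit recovered 74% of changed genes in the striatal and 66% in the cerebellar Eed comparison. At a log2 change of 2 it recovered 98% and 94%. At 9 months alone, 15% and 18% were recovered at a log2 change of 1, and 69% and 80% at 2. False calls were 13 in striatum and 7 in cerebellum, and 8 and 6 at 9 months alone. Variation shared by the genes of a library was not simulated. With 200 changed genes the adjusted threshold is also easier to pass, so these shares may exceed those in the measured data.

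Computations used R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.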

Results

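Microglia are the resident macrophages of the brain. Their translated RNA was measured by translating ribosome affinity purification (TRAP), in which ribosomes tagged with green fluorescent protein are captured from a chosen cell type together with the RNA they carry. In these mice, a tamoxifen-inducible Cre under the Cx3cr1 promoter turned on the tagged ribosomal protein, and the labels state that tamoxifen was given at 4-6 weeks of age. The same Cre acted on floxed Eed in the libraries labelled Eed-ko. Eed is a core subunit of Polycomb repressive complex 2 (PRC2), which places the repressive mark H3K27me3. The series holds 97 samples, of which 28 have values in the deposited table. These are 24 TRAP libraries, 2 for each combination of region (striatum or cerebellum), age (3, 6 or 9 months) and genotype (control or Eed-ko), and 4 libraries of 9-month tissue RNA, 2 per region. All 4 tissue RNA libraries are of control genotype. The labels describe the tissue RNA as the fraction left unbound by the TRAP capture. The other 69 samples, single nuclei and chromatin immunoprecipitation, have no values in the deposited table and were not analysed here.

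The TRAP libraries held 20.7 to 177 M recovered reads (M, mega), and the tissue libraries 20.2 to 54.6 M. Depth was 24.2 to 35.4 M at 3 months, 49.8 to 97.4 M at 6 months and 20.7 to 177 M at 9 months. The largest ratio between libraries of 1 group was 8.29, in cerebellar 9-month Eed-ko, with 21.4 and 177 M. Between 11734 and 13163 genes reached 1 RPKM in a library. Libraries of 1 group correlated across genes with r of 0.92 to 0.971 for TRAP and 0.981 to 0.982 for tissue RNA.

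Which transcripts the capture enriched was asked by setting 9-month control TRAP libraries against tissue RNA (n = 2 each). In striatum, Bin2, a membrane-shaping protein of myeloid cells, rose from 2.62 ± 0.58 RPKM in tissue to 469 ± 87.8 in TRAP. Fcer1g, an adaptor of Fc receptors, C1qc of the complement cascade, Lgals9 and Ly86 rose by log2 changes of 6.79, 6.65, 6.58 and 6.55. In cerebellum, Fcer1g rose from 6.61 ± 2.84 to 1378 ± 303 RPKM, and Bahcc1, Ly86, the adaptor Tyrobp and C1qc rose by 7.20, 7.16, 7.12 and 6.87. Transcripts of other brain cells fell in striatal TRAP, among them Sparcl1 and Gpr37l1, both glial, the apolipoprotein gene Apod and mitochondrial Chchd10, with log2 changes of -3.29, -3.52, -3.38 and -3.73. A copy of the small RNA U6 fell by -3.52 there. In cerebellar TRAP, the largest falls were in genes of small noncoding RNAs, snoU109, n-R5s8, U6 and U3, and U3 kept its call in 3 of 8 alternative settings.

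All 22 homeostatic microglia genes rose in TRAP in both regions, with a median log2 change of 5.51 in striatum and 5.11 in cerebellum. The lysosome list had 20 of 24 members higher and 1 lower in striatum and 19 higher and 1 lower in cerebellum. Clearance receptors and opsonins had 17 of 29 higher and 4 lower in striatum and 21 higher and 1 lower in cerebellum. MHC class II genes, which present antigen, had 5 of 7 higher in striatum and 7 of 7 in cerebellum, and border macrophage genes 7 and 11 of 11. Of the 16 neuronal genes, 13 fell in striatum and 9 in cerebellum, while 1 rose in each. Astrocyte genes fell for 10 of 12 members in striatum and 5 in cerebellum, and oligodendrocyte genes for 13 of 14 and 11. The camera adjusted p for the homeostatic list was 9.88e-20 in striatum and 4.12e-23 in cerebellum. No list kept its call in either region with an estimated correlation, where the homeostatic adjusted p = 0.216 and adjusted p = 0.137 with an estimated correlation.

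In limma's test, 6423 of 14186 genes differed between TRAP and tissue in striatum (2748 higher, 3675 lower) and 3901 in cerebellum (2110 higher, 1791 lower). Without striatum tissue replicate 1 or 2 the striatal count was 4091 or 4026, and without cerebellum tissue replicate 1 or 2 the cerebellar count was 1828 or 1708. With both regions required, 1248 genes were TRAP-enriched.

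Neuronal RNA was present in every TRAP library, and the level of homeostatic microglial transcripts relative to it differed by region. Less microglial RNA and lower expression of homeostatic genes in microglia would both raise the carry-over score, which cannot tell them apart. The carry-over score, neuronal minus homeostatic, was -2.86 ± 0.29 in striatal and -1.25 ± 0.45 in cerebellar control libraries (n = 6 each, exact permutation p = 0.00216, the smallest possible, adjusted p = 0.00691). The difference of 1.61 came mostly from homeostatic genes, with a mean of 8.38 ± 0.05 in striatum and 6.87 ± 0.33 in cerebellum, while the neuron list had 5.52 ± 0.28 and 5.61 ± 0.18 (exact permutation p = 0.502, adjusted p = 0.574). Eed-ko libraries scored -2.42 ± 0.52 in striatum (exact permutation p = 0.104 against controls, adjusted p = 0.139, n = 6 each) and -0.47 ± 0.85 in cerebellum (exact permutation p = 0.0758, adjusted p = 0.11, n = 6 each).

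**Figure D1:**
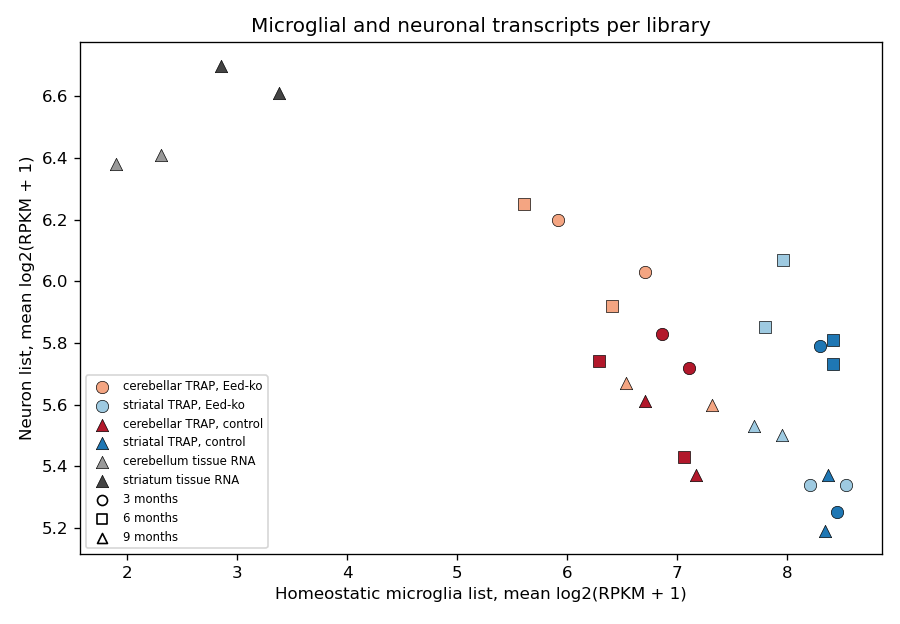
Mean log2(RPKM + 1) of the homeostatic microglia list (x axis) against that of the neuron list (y axis) in each of the 28 libraries, coloured by region, genotype and assay, with the age as the symbol. Tissue RNA libraries lie at the left, striatal control TRAP libraries at the right with a mean of 8.38, and cerebellar control TRAP libraries between them with a mean of 6.87.

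The question of the series is how microglia of different brain regions differ, and cerebellar control TRAP libraries were set against striatal ones (n = 6 each, 2 at each of 3 ages). The largest differences were in genes of regional neurons. Car8 of Purkinje cells had 0.727 ± 0.466 RPKM in striatum and 522 ± 129 in cerebellum, a log2 change of 8.25 ± 0.18. Gabra6, a receptor subunit of granule cells, and Cbln3, which granule cells secrete, rose by 7.05 and 7.03, and Zic1, Ppp1r17, Neurod1, Bcl2l15, Pcp2, Fat2 and Lhx1 by 5.89 to 4.78. The dopamine receptors Drd2 and Drd1a of striatal projection neurons fell, Drd2 from 41.7 ± 11.3 to 0.271 ± 0.337 RPKM (log2 change -5.07 ± 0.24). Ctxn1, Tac1, Ddn, Nrgn, Kcnip2, Neto1 and Rgs4, neuronal genes rich in the forebrain, fell by -5.32 to -4.37. All 16 cerebellar neuron genes rose (camera adjusted p = 1.15e-23, adjusted p = 0.00213 with an estimated correlation) and all 15 striatal neuron genes fell (camera adjusted p = 2.28e-20, adjusted p = 0.0209 with an estimated correlation).

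Homeostatic microglia genes were lower in cerebellum, with 20 of 22 members down and none up, the same 20 and 0 when adjusted over the list alone. Cx3cr1, the fractalkine receptor, had 165 ± 14.3 RPKM in striatum and 50.4 ± 16.5 in cerebellum, a log2 change of -1.75 ± 0.22. The fructose transporter Slc2a5, the transcription factor Mef2c, the matrix protein Sparc and the Fc receptor-like Fcrls fell by -2.41, -1.82, -1.63 and -2.21. The list median was -1.57 (camera adjusted p = 3.17e-14, but adjusted p = 0.292 with an estimated correlation). Rescaling the libraries to the TRAP-enriched genes, whose own median was -0.68, left the homeostatic median at -0.90.

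Genes that clear debris went both ways, with 9 of 30 clearance receptors and opsonins up and 14 down (10 and 14 adjusted over the list alone; camera adjusted p = 0.272). The receptor Mertk, its ligand Pros1 and the integrin Itgav fell by -1.21, -1.27 and -0.81, and the scavenger receptor Colec12 rose by 1.70. Of 25 lysosome genes, 17 fell, among them Ctsa, Ctsl, Laptm5 and Psap with log2 changes of -1.17, -1.23, -1.43 and -0.87 (17 adjusted over the list alone; camera adjusted p = 1.55e-05, adjusted p = 0.417 with an estimated correlation). Of 12 cytokine genes, 5 fell, and Nlrp3 of the inflammasome, Il1a, Il6 and Il18 had -1.47, -1.25, -0.85 and -1.14 (5 adjusted over the list alone; camera adjusted p = 0.0475, adjusted p = 0.417 with an estimated correlation). After rescaling to the TRAP-enriched genes the medians of these lists turned from -0.40 to 0.27 for clearance, from -0.60 to 0.06 for lysosome and from -0.40 to 0.27 for cytokines.

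Some MHC class II and border macrophage genes were higher in cerebellum. Among 7 class II genes 4 rose (4 adjusted over the list alone; camera adjusted p = 0.268). They were H2-Aa with 8.08 ± 11.8 and 41.3 ± 18.2 RPKM, H2-Eb1, H2-Ab1 and the invariant chain Cd74 with 50.8 ± 33.8 and 170 ± 64.1, by log2 changes of 2.90, 2.58, 1.78 and 1.88. Border macrophages, which live along vessels and meninges, had 8 of 12 genes up, including Lyve1 (5.32 ± 5.2 and 44 ± 25.4 RPKM), Cd163, Cd209f and Folr2, and 10 when adjusted over the list alone (camera adjusted p = 0.00675, adjusted p = 0.711 with an estimated correlation). One cerebellar control library, 6-month replicate 2, had Lyve1 at 0.123 and Mrc1 at 0.718 RPKM, far below the other cerebellar controls.

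Of 22 Polycomb genes, 8 were up and 3 down in cerebellum (10 and 3 adjusted over the list alone; camera adjusted p = 0.0665). Ezh2, the catalytic subunit of PRC2, had 2.65 ± 0.838 and 6.39 ± 0.977 RPKM (log2 change 1.04 ± 0.21), Suz12 rose by 0.33 and the PRC2 cofactor Jarid2 by 1.84. The demethylases of the same mark, Kdm6a and Kdm6b, rose by 1.51 and 1.85, and Cbx2 by 1.85. Eed had 21.7 ± 5.8 and 20.5 ± 2.4 RPKM (log2 change -0.04, adjusted p = 0.843), and rose by 0.63 after rescaling to the TRAP-enriched genes (adjusted p = 0.00931).

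Among the other lists, the interferon response had 3 of 19 up, Stat2, Ifi27l2a and Ifitm3 by 1.16, 1.60 and 1.42, and Xaf1 down by -0.54 (3 and 1 adjusted over the list alone; camera adjusted p = 0.605). Disease-associated microglia genes split, with 6 of 21 up and 4 down (6 and 4 adjusted over the list alone; camera adjusted p = 0.876), Axl at 1.49 and Timp2, Cd9 and Lpl at -0.82, -1.23 and -1.03. MHC class I had 1 of 10 up, Nlrc5 at 0.57, and 2 down, Psmb8 at -0.83 and Tapbp at -0.62 (1 and 1 adjusted over the list alone; camera adjusted p = 0.621). Developmental transcription factors, 23 of 70 measured, had 4 up and 2 down (3 and 2 adjusted over the list alone; camera adjusted p = 0.361), with Lhx1, Otx2 and Pax2 at 4.78, 2.03 and 1.44 and Isl1 at -1.13. Cell cycle inhibitors had 1 of 6 up, Cdkn1b at 1.15, and 1 down, Cdkn1c at -1.11 (1 and 1 adjusted over the list alone; camera adjusted p = 0.84). Proliferation genes had 3 of 17 down, Mki67, Mcm6 and Ccnb1 at -1.10, -0.81 and -0.49 (2 adjusted over the list alone; camera adjusted p = 0.0665), though Ccnb1 had 0.17 after rescaling to the TRAP-enriched genes. Xaf1 and Tapbp turned to 0.12 and 0.05 by that rescaling. It also turned the medians from -0.43 to 0.24 for proliferation, from -0.14 to 0.53 for MHC class I and from -0.25 to 0.41 for cell cycle inhibitors.

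Markers of other brain cells moved with region as well. Astrocyte genes had 10 of 12 up and 1 down, with Aldoc at 25.2 ± 6.49 and 185 ± 39.1 RPKM and S100b, Aqp4 and Slc4a4 at log2 changes of 2.22, 2.55 and 1.81 (camera adjusted p = 1.55e-05, adjusted p = 0.111 with an estimated correlation). Choroid plexus genes had 4 of 5 up, Otx2, Kl, Clic6 and Ttr (5 adjusted over the list alone; camera adjusted p = 0.0227, adjusted p = 0.417 with an estimated correlation). Neuronal genes had 5 of 16 up and 3 down (camera adjusted p = 0.863), with Stmn2, Rbfox3 and Snap25 at 2.13, 1.42 and 1.27 and Camk2a at -2.46. Mural cell and fibroblast genes had 5 of 11 up, including Dcn and Vtn at 2.05 and 1.47 (camera adjusted p = 0.0869). Oligodendrocyte genes had 1 of 14 up and 3 down, Cspg4, Mobp and Opalin at -1.26, -0.49 and -0.87 (camera adjusted p = 0.746). Mobp turned to 0.18 after rescaling to the TRAP-enriched genes. No member of the endothelial list (11 measured, camera adjusted p = 0.863) or of the list of monocytes, neutrophils and lymphocytes (7 measured, camera adjusted p = 0.928) passed limma's test, and the smallest adjusted p in each were those of Pecam1 (log2 change -0.47) and Cd79b (-0.59). Immediate early and heat shock genes had 2 of 11 up, Dusp1 at 1.76 among them, and 4 down, including Egr1, Fosb and Junb (3 and 4 adjusted over the list alone; camera adjusted p = 0.761). Of 5 sex-linked genes, Uty rose by 0.44 (camera adjusted p = 0.84).

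In all, 5971 of 16090 genes differed between the regions in limma's test, 3092 higher and 2879 lower in cerebellum. Rescaling each library to the TRAP-enriched genes brought the median of all genes to 0.67 and the split to 8807 higher and 633 lower.

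The region difference was therefore also computed among the 1248 TRAP-enriched genes alone, rescaled to their own median, a choice made after the data were seen. P2ry12, a purinergic receptor by which homeostatic microglia sense nucleotides, had 1004 ± 81.3 RPKM in striatum and 243 ± 57.3 in cerebellum (n = 6 each), a log2 change of -1.41 ± 0.13 after rescaling. Mn1, Kalrn, Upk1b, Slc2a5, Bank1, Fcrls, Crybb1, Fam167b and Npl fell by -3.02 to -1.39, and 20 of 22 homeostatic genes fell while 1 rose (camera adjusted p = 1.25e-10, adjusted p = 0.0589 with an estimated correlation). Lyve1 rose by 3.16 ± 0.55, the platelet factor Pf4 by 2.68, Cd74 by 2.55 ± 0.33 and H2-Ab1 by 2.45. Marveld2, Slc16a13, Bahcc1, Hic2, Kdm6b and Tnrc6a rose by 3.20 to 2.50.

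By list, all 7 border macrophage genes among the enriched rose, Mrc1, F13a1 and Ms4a7 by 2.11, 2.22 and 1.56 (camera adjusted p = 0.00158, adjusted p = 0.288 with an estimated correlation). All 4 interferon response genes rose, Ifitm3 by 2.09 and Ifi27l2a by 2.27 (camera adjusted p = 0.0129, adjusted p = 0.288 with an estimated correlation). The others, Rtp4 and Bst2, rose by 0.99 and 0.81 and did not pass in the test of all genes without rescaling. Of 17 clearance genes, 4 rose and 6 fell (camera adjusted p = 0.469). The scavenger receptors Cd36 and Msr1 and the lectin Clec7a rose by 1.73, 1.99 and 1.33 and Mertk fell by -0.55. Of 5 class II genes, 3 rose (camera adjusted p = 0.0841), and of 15 lysosome genes, 2 rose and 3 fell. H2-DMa and Npc2, at 0.37 and 0.38, rose only by the rescaling and had -0.29 each without it. In total 599 genes differed (313 higher, 286 lower), against 820 without rescaling (91 higher, 729 lower), and 566 (289 higher, 277 lower) between the regions in Eed-ko libraries.

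**Figure D2:**
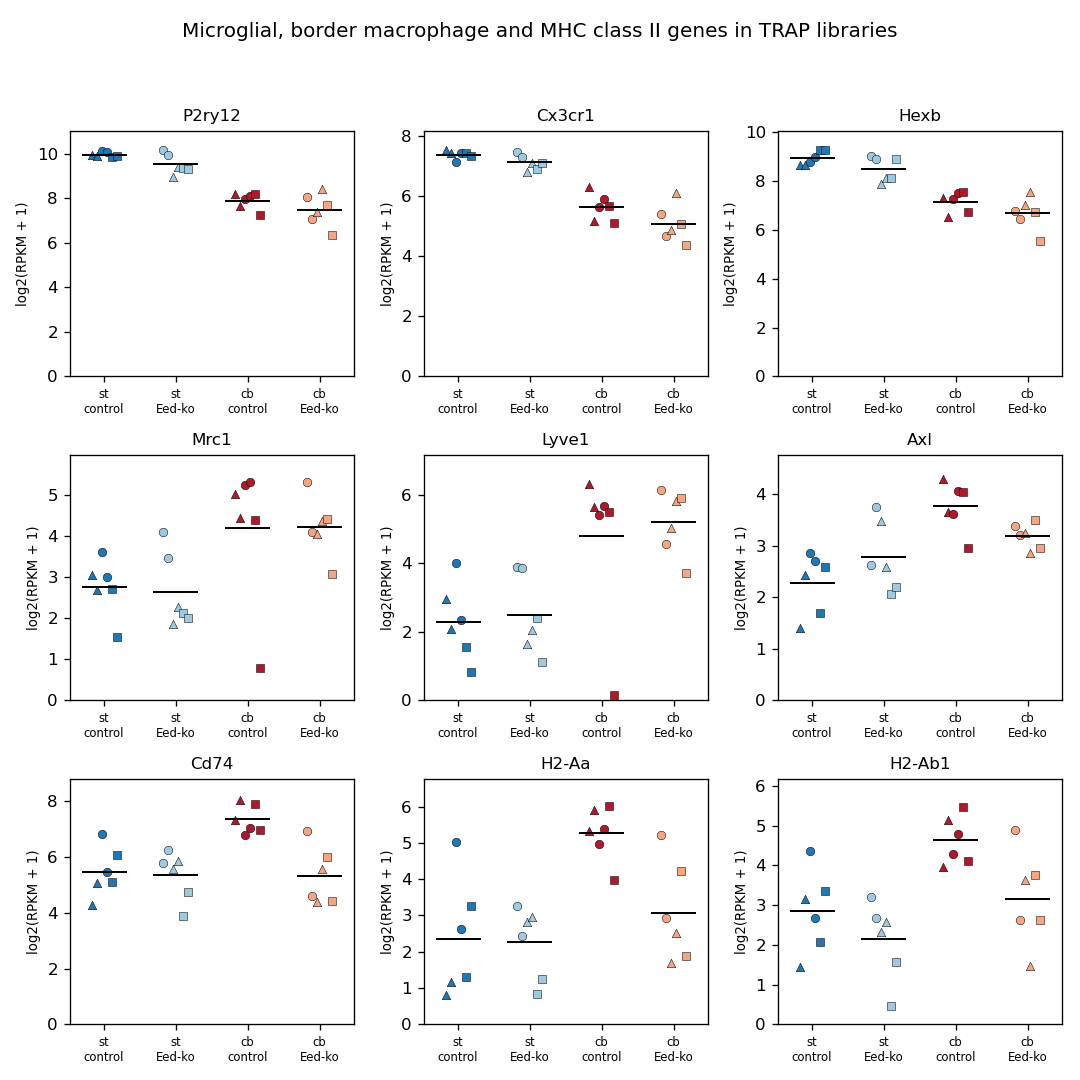
log2(RPKM + 1) of 9 genes in each TRAP library, by region (st, striatum; cb, cerebellum) and genotype, with circles, squares and triangles for 3, 6 and 9 months and a bar at the mean of 6 libraries. P2ry12 averaged 1004 RPKM in striatal and 243 in cerebellar controls, and Cd74 averaged 170 RPKM in cerebellar controls and 49.1 in cerebellar Eed-ko.

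The effect of Eed loss in striatal microglia was asked by comparing Eed-ko with control libraries over the 3 ages (n = 6 each). The developmental transcription factors Tbx15 and Hoxd8 (ENSMUSG00000027868 and ENSMUSG00000027102), near 0 in controls at 0.0326 ± 0.0474 and 0.0287 ± 0.0384 RPKM, averaged 3.75 ± 5.04 and 2.61 ± 3.44 in Eed-ko (log2 changes 1.50 ± 0.22 and 1.27 ± 0.16). Mab21l2 rose by 1.56, Gata2 by 1.28 and the stress-induced Ddit4 by 1.30, from 8.91 ± 6.77 to 27.2 ± 26.7 RPKM. The metallothionein Mt2, the growth arrest transcript Gas5, the ganglioside synthase St8sia1 and Car8 and Zic1, both of the cerebellar neuron list, rose by 1.00, 0.79, 0.70, 1.01 and 0.92. Ifi30, a lysosomal thiol reductase of antigen processing, fell from 46.7 ± 8.97 to 20.8 ± 7.34 RPKM (log2 change -1.18 ± 0.22). Tbx15 kept its call in 16 of 22 alternative settings and Hoxd8 in 16 of 21. Of 22, Car8 kept it in 7, Ddit4 and Gas5 in 6, Mt2, Zic1 and St8sia1 in 5, and Mab21l2 and Ifi30 in 4. Outside the naming rule, 4 genes of low or repeated annotation fell, Gm13394, Gm6430, Gm12832 and SNORA70.

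Developmental transcription factors had 3 of 23 members up and 11 when adjusted over the list alone (camera adjusted p = 7.56e-11, adjusted p = 0.0313 with an estimated correlation). No member of the homeostatic, interferon or lysosome list, none of which holds Ifi30, passed the test alone, with 0, 4 and 2 lower when adjusted over the list alone and camera adjusted p of 3.7e-08, 3.61e-07 and 3.7e-08, but adjusted p = 0.276, adjusted p = 0.219 and adjusted p = 0.219 with an estimated correlation. Their medians were -0.36, -0.43 and -0.32, and -0.12, -0.19 and -0.07 after rescaling to the TRAP-enriched genes. Striatal neuron and oligodendrocyte genes had medians of 0.40 and 0.30 (camera adjusted p of 8.33e-08 and 0.000621, both with adjusted p = 0.219 with an estimated correlation), and 5 oligodendrocyte genes were higher when adjusted over the list alone. Eed itself had 21.7 ± 5.8 RPKM in controls and 26.1 ± 6.8 in libraries labelled Eed-ko (log2 change 0.26 ± 0.13, adjusted p = 0.437). Ezh2, Suz12 and Cx3cr1 had 0.18, 0.24 and -0.27, none past the test.

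In limma's test 17 genes differed, 12 higher and 5 lower, with 1985 at an unadjusted p under 0.05, but 0 with the carry-over score as a covariate (751 at an unadjusted p under 0.05), 1 with blocks by title number and 4 in a fit of the striatal libraries alone. Quantile normalization gave 2 higher and 2 lower, and rescaling to the TRAP-enriched genes, which brought the median of all genes to 0.26, gave 15 and 1. With single libraries left out, the count was 8 without either 3-month control, 3 and 10 without 3-month Eed-ko replicates 1 and 2, 5 without 6-month control replicate 1, 8 without replicate 2, and 9 and 7 without the 6-month Eed-ko replicates. It was 13 and 11 without 9-month control replicates 1 and 2, and 5 and 124 without 9-month Eed-ko replicates 1 and 2.

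The same comparison was made in cerebellar microglia (n = 6 each). Cd74 (ENSMUSG00000024610), the class II invariant chain, fell from 170 ± 64.1 to 49.1 ± 39.5 RPKM, a log2 change of -2.02 ± 0.39. H2-DMa, which loads peptides onto class II, fell from 54.7 ± 17.3 to 27.8 ± 11.8 (log2 change -0.98 ± 0.20). The interferon-induced Ifi27l2a, the adaptor Lat2 and the lysosomal sterol carrier Npc2 fell by -1.70, -1.26 and -0.94, and the oxidase subunit Cyba from 33.6 ± 11.5 to 16.7 ± 6.8 RPKM. Fam89a, Tmem71, Klra2, Slfn2, Fxyd5 and Psmg4 fell by -1.37 to -0.99. The let-7 repressor Lin28b rose from 9.97 ± 3.98 to 33.7 ± 20.6 RPKM (log2 change 1.47 ± 0.21), the imprinted gene Zdbf2 rose by 1.29 and Hoxd8 by 1.01. Slc39a12, Gja1 and Tdo2 rose by 1.24, 1.04 and 0.85, Gja1 as a member of the astrocyte list, and Amy1, Fam171a1, Nsg2 and Cadm2 by 1.04, 0.78, 0.70 and 0.69. Lin28b and Zdbf2 kept their call in 18 of 22 alternative settings, Fam89a in 13 and Cd74 in 10. Slc39a12, Tdo2 and Fxyd5 kept it in 7 and Klra2 in 6.

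Of 7 class II genes, 2 fell over all genes tested and 7 when adjusted over the list alone, with a median of -1.46 (camera adjusted p = 1.65e-07, adjusted p = 0.116 with an estimated correlation). H2-Eb1 and H2-Aa had -2.25 and -2.18, with adjusted p of 0.0644 and 0.0686. MHC class I genes had none past the test and 5 of 10 lower when adjusted over the list alone (median -0.51, camera adjusted p = 8.46e-05, adjusted p = 0.118 with an estimated correlation). Homeostatic genes had none past the test and 10 of 22 lower when adjusted over the list alone (median -0.50, camera adjusted p = 1.65e-07, adjusted p = 0.263 with an estimated correlation). Lysosome genes had 1 lower, Npc2, and 8 adjusted over the list alone (median -0.36, camera adjusted p = 3.52e-07), and interferon genes 1 lower, Ifi27l2a, and 3 adjusted over the list alone (median -0.40, camera adjusted p = 0.000207), each with adjusted p = 0.263 with an estimated correlation. After rescaling to the TRAP-enriched genes these medians were -1.06 for class II, -0.11 for class I, -0.09 for homeostatic, 0.05 for lysosome and 0.01 for interferon genes, and the border macrophage median was -0.09 before and 0.32 after.

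Markers of other cells moved in the same libraries. Of the neuronal genes, Thy1 rose from 32.9 to 51.2 RPKM (log2 change 0.67, adjusted p = 0.0407), 4 were higher adjusted over the list alone, and the median was 0.29 (camera adjusted p = 5.26e-07, adjusted p = 0.145 with an estimated correlation). Astrocyte genes had 1 up and 4 adjusted over the list alone (median 0.22, camera adjusted p = 0.000207, adjusted p = 0.145 with an estimated correlation). After rescaling to the TRAP-enriched genes the neuronal and astrocyte medians were 0.70 and 0.63. The carry-over score was 0.78 higher in Eed-ko, of which the mean of the neuron list made up 0.33. Developmental transcription factors had 1 up and 3 adjusted over the list alone (camera adjusted p = 3.86e-05, adjusted p = 0.145 with an estimated correlation). Eed had 20.5 ± 2.4 RPKM in controls and 28.1 ± 2.18 in libraries labelled Eed-ko (log2 change 0.44 ± 0.13, adjusted p = 0.123), and Ezh2, Suz12 and Cx3cr1 had -0.14, -0.10 and -0.55, none past the test.

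Here 60 genes differed in limma's test, 20 higher and 40 lower, with 2383 at an unadjusted p under 0.05 and 5 by voom on recovered reads. Rescaling to the TRAP-enriched genes brought the median of all genes to 0.40 and gave 866 higher and 15 lower, and with the carry-over score as a covariate 2 genes passed. In a fit of the cerebellar libraries alone limma called 0, with 1829 at an unadjusted p under 0.05. The count without 3-month control replicates 1 and 2 was 7 and 8, without 3-month Eed-ko replicates 154 and 1, without 6-month controls 11 and 290, and without 6-month Eed-ko 142 and 5. Without 9-month controls it was 5 and 224, and without 9-month Eed-ko 11 and 376.

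Whether Eed loss acted differently in the regions was tested as an interaction. MHC class II genes had a median difference of -0.83, cerebellum minus striatum (camera adjusted p = 0.00105, adjusted p = 0.758 with an estimated correlation), with 3 of 7 lower when adjusted over the list alone. Disease-associated genes had -0.42 (camera adjusted p = 0.0316) and neuronal genes 0.26 (camera adjusted p = 0.00235), each with adjusted p = 0.793 with an estimated correlation. Eed, Ezh2, Suz12 and Cx3cr1 had 0.18, -0.32, -0.34 and -0.28. No single gene passed limma's test, with 1380 at an unadjusted p under 0.05 and 0 by voom, but 47 passed without the filter on low values (21 higher, 26 lower) and 1 gene passed without striatal 3-month control replicate 2.

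Across 16090 genes, the Eed effects in the regions correlated with r = 0.26 (covariance 0.0238), against 0 in simulations without effects. Hoxd8 rose in both regions, where 0.0149 shared rises would be expected by chance, and Gm6430 and Gm13394 fell in both (0.0124 expected), which rests on the 3-month controls, the TRAP libraries where Gm13394 stood at 24.5 to 27.3 RPKM. These expectations and the simulated 0 assume that the regions share no animals, which the labels leave open. The simulated noise was also independent between genes and libraries, so the 0 was fixed in advance. The carry-over score was higher in Eed-ko in both regions, by 0.44 in striatum and 0.78 in cerebellum. Whether this alone gives the r of 0.26 was not tested. The Eed effect in striatum and the region difference share the striatal controls. Their r was 0.29 with a covariance of 0.0641, against a simulated r of 0.50 and covariance of 0.0268, and with the controls split so that none was shared, r was 0.16 (0.10 to 0.20) and the covariance 0.0415. Genes are not independent replicates, so these values carry no p.

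The region difference in Eed-ko microglia (n = 6 each) again led with neuronal genes. Car8 had 2.64 ± 1.53 and 619 ± 203 RPKM, Gabra6, Cbln3, Ppp1r17 and Neurod1 rose by 7.24 to 5.66, and Ddn, Tac1, Ctxn1 and Drd2 fell by -5.45 to -4.77. All 22 homeostatic genes fell (median -1.60, camera adjusted p = 6.15e-15, adjusted p = 0.296 with an estimated correlation), with a median of -0.77 after rescaling to the TRAP-enriched genes. Of the clearance genes, 15 fell and 4 rose (camera adjusted p = 0.0302, adjusted p = 0.617 with an estimated correlation), a median of -0.67 that was 0.17 after that rescaling. Class II genes had a median of -0.03, and 0.81 after that rescaling. Border macrophages had 5 up and 7 adjusted over the list alone (camera adjusted p = 0.0184, adjusted p = 0.617 with an estimated correlation). In total 6170 genes differed in limma's test, 2991 higher and 3179 lower, and 10532 and 576 after rescaling, which brought the median of all genes to 0.81.

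By age, limma's test of Eed loss called the most genes at 9 months (n = 2 each), but this order depended on the setting in both regions. With limma fitted to the libraries of 1 region and age alone, 3, 0 and 0 genes passed in striatum at 3, 6 and 9 months and 9, 0 and 0 in cerebellum, and without the filter on low values 164, 50 and 45 in cerebellum. In striatum, Tbx15 rose from 0.00415 ± 0.00587 to 10.1 ± 2.18 RPKM, Hoxd8 from 0.0113 ± 0.016 to 6.96 ± 1.33 and Mab21l2 from 0.15 ± 0.212 to 11.5 ± 3.73, with log2 changes of 3.45 ± 0.39, 2.97 ± 0.28 and 3.42 ± 0.50. The cell cycle inhibitors Cdkn2b and Cdkn2a, textbook Polycomb targets, rose from 0.268 ± 0.379 to 8.29 ± 3.82 and from 0.186 ± 0.226 to 2.81 ± 0.217 (log2 changes 2.84 ± 0.43 and 1.69 ± 0.27). Hoxc4 and Hoxd13 were listed at 0 in both controls and averaged 5.7 ± 3.28 and 3.27 ± 0.683 in Eed-ko. Serpinf1, a secreted neurotrophic and anti-angiogenic factor, rose from 15.5 ± 4.3 to 105 ± 2.27. Ccrl2, a chemerin-binding receptor, Ifi30, Ccdc86, coagulation factor gene F9 and Psme2b-ps fell by -2.01 to -1.77. Tbx15, Hoxd8, Mab21l2 and Serpinf1 kept their call in 9 of 11 alternative settings and Cdkn2b in 7. Ccrl2, Ccdc86 and Psme2b-ps kept it in 5, Ifi30 in 4 and F9 in 2.

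Of 23 developmental transcription factors, 10 rose in striatum at 9 months and 15 when adjusted over the list alone (camera adjusted p = 4.4e-18, adjusted p = 0.00385 with an estimated correlation). They were Hoxa10, Hoxc4, Hoxc6, Hoxc8, Hoxc10, Hoxd8, Hoxd13, Gata2, Otx2 and Tbx15. The list median was 1.05, below that of 5 choroid plexus genes, 1.29, of which Otx2 alone passed (camera adjusted p = 0.0144, adjusted p = 0.457 with an estimated correlation), and that of endothelial genes was 0.69 (camera adjusted p = 0.193). Cell cycle inhibitors had 2 of 6 up and 3 adjusted over the list alone (camera adjusted p = 0.00809, adjusted p = 0.285 with an estimated correlation). The homeostatic and lysosome medians were -0.51 and -0.45 and that of striatal neurons was 0.59 (camera adjusted p of 1.53e-05, 8.15e-05 and 0.000343, each with adjusted p = 0.457 with an estimated correlation), and -0.13, -0.06 and 0.98 after rescaling to the TRAP-enriched genes. In cerebellum at 9 months, Hoxd8 was listed at 0 in both controls and averaged 6.45 ± 2.77 RPKM in Eed-ko, as did Hoxc10 with 2.27 ± 0.24, and Tbx15 had 0.0595 ± 0.0319 and 3.06 ± 0.15. Magee2, Reep4, Khdrbs3 and Cela1 rose by 3.48 to 2.34, and Nradd, Tmem160, the nucleotide reductase Rrm2, Fam89a and the cell death gene Bad fell by -2.36 to -1.81. Over 11 alternative settings, Hoxd8 kept its call in 10, Bad in 8, Khdrbs3 in 7 and Magee2 and Tmem160 in 6. Rrm2 kept it in 4, Fam89a in 3, Reep4 in 2 and Cela1 and Nradd in 1. Developmental transcription factors had 3 up and 9 adjusted over the list alone (camera adjusted p = 2.7e-09, adjusted p = 0.0548 with an estimated correlation). Cdkn2a and Cdkn2b had log2 changes of 0.48 and 0.26 in cerebellum, with adjusted p of 0.538 and 0.908. Class II genes had a median of -2.01 with 4 of 7 lower when adjusted over the list alone (camera adjusted p = 0.000242, adjusted p = 0.312 with an estimated correlation).

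At 9 months 89 genes differed in striatum in limma's test (72 higher, 17 lower) and 55 in cerebellum (39 higher, 16 lower), and Hoxc10, Hoxd8 and Tbx15 rose in both (0.175 expected if no animals are shared). Rescaling to the TRAP-enriched genes brought the medians of all genes to 0.40 and 0.28 and gave 92 higher and 1 lower in striatum and 12 and 1 in cerebellum, and voom called 205 and 162. Without 9-month Eed-ko replicates 1 and 2 the striatal count was 58 and 512 and the cerebellar one 50 and 247, and without control replicates 1 and 2 these were 35 and 43, and 33 and 150. With the carry-over score as a covariate limma called 0 genes in striatum (750 at an unadjusted p under 0.05) and 55 in cerebellum, and Tbx15 in striatum had 3.52 ± 0.66 in place of 3.45 ± 0.39. Blocks by title number gave 39 and 11, and limma fitted to the 4 libraries of 1 region and age alone called 0 in both, with 1875 and 631 at an unadjusted p under 0.05.

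At 3 months, 2 genes passed in striatum, Gm6430 and Gm13394, named after their values were seen because they fall outside the rule, with log2 changes of -3.56 and -4.64. In cerebellum 4 passed, the same pair at -2.47 and -4.52, Gm11987 at -2.41 and a 5S_rRNA copy at 2.32. The striatal count was 29 without 3-month control replicate 2 and 5 without either 3-month Eed-ko library, and the cerebellar one was 30 without control replicate 1 and 8 without Eed-ko replicate 2. At 6 months, 4 genes passed in striatum, Gm17566, Gm16146, Gm12832 and SNORA70, also chosen after their values were seen, and 19 in cerebellum (6 higher, 13 lower), among them Krtcap2, Lrrc20, Alg3 and Med11 with -1.78, -1.76, -1.71 and -1.65. Of 11 alternative settings, Krtcap2 kept its call in 7, Alg3 in 6, Med11 in 5 and Lrrc20 in 2. Rescaling to the TRAP-enriched genes gave 0 in striatum and, in cerebellum, 5 higher and 0 lower. The striatal count was 11 without 6-month Eed-ko replicate 1 or control replicate 1 and 31 without Eed-ko replicate 2, and the cerebellar one was 40 without Eed-ko replicate 1 and 38 and 61 without control replicates 1 and 2. Striatal neuron genes had a median of 0.88 at 6 months in striatum, with 11 of 15 higher when adjusted over the list alone (camera adjusted p = 2.88e-12, adjusted p = 0.184 with an estimated correlation), and the homeostatic median there was -0.56. These medians were 0.86 and -0.36 with quantile normalization and 1.24 and -0.20 after rescaling to the TRAP-enriched genes.

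**Figure D3:**
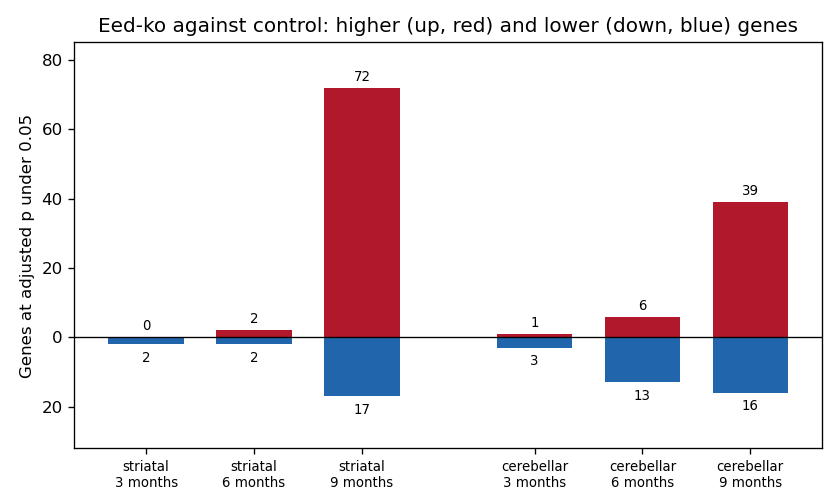
Number of genes higher (red, above 0) or lower (blue, below 0) in Eed-ko than in control TRAP libraries in limma's test at an adjusted p under 0.05, for each region and age with 2 libraries per group. The bars are tallest at 9 months, with 72 and 17 in striatum and 39 and 16 in cerebellum.

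A test of whether the Eed effect changed with age named 9 genes in striatum and 6 in cerebellum, but 2 and 2 in fits of 1 region alone, 2 and 1 with blocks by title number, 4 and 3 with a pseudocount of 0.1 RPKM and 99 and 118 without the filter on low values. Hoxd8 had log2 changes of 0.77, 0.08 and 2.97 at 3, 6 and 9 months in striatum (adjusted p = 0.0124), and 0.15, 0.04 and 2.85 in cerebellum (adjusted p = 0.00776). Tbx15, with 0.89, 0.15 and 3.45, and Cdkn2b, with -0.11, -0.78 and 2.84, also passed in striatum, as did Hoxc4 and Hoxd13 (adjusted p = 0.0473 for each). Tbx15 and Cdkn2b each kept their call in 3 of 19 alternative settings. Ddt passed in cerebellum (adjusted p = 0.0144). The others were Gm13394, Gm6430, Gm12832 and Snora34 in striatum, and Gm13394, Gm6430, Gm11987 and a U6 copy in cerebellum. Voom called 0 genes in either region, where limma had 1136 and 1199 at an unadjusted p under 0.05. Age cannot be told apart from sex of the animals here, since the 9-month libraries differ in Y-linked transcripts. The 3-month libraries come from another run format, which cannot be told apart from age at 3 months. The 6- and 9-month libraries share their format, so it does not separate these ages. Whether they shared a run is not given. Their library names end in a sample number that restarts for each region and genotype. Genotype could therefore coincide with run at 6 and 9 months, which the labels do not settle. At 3 months, Eed-ko and control libraries of a region carried the same lane numbers. The striatal count moved to 4 without either 3-month Eed-ko library, 5 and 21 without 3-month control replicates 1 and 2, 2 without 6-month or 9-month control replicate 2, and 14 and 31 without the 9-month Eed-ko replicates. The cerebellar one moved to 14 without 3-month control replicate 1, 10 without either 6-month Eed-ko library, 13 and 12 without the 6-month controls, 13 and 34 without 9-month Eed-ko and 12 and 25 without the 9-month controls.

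**Figure D4:**
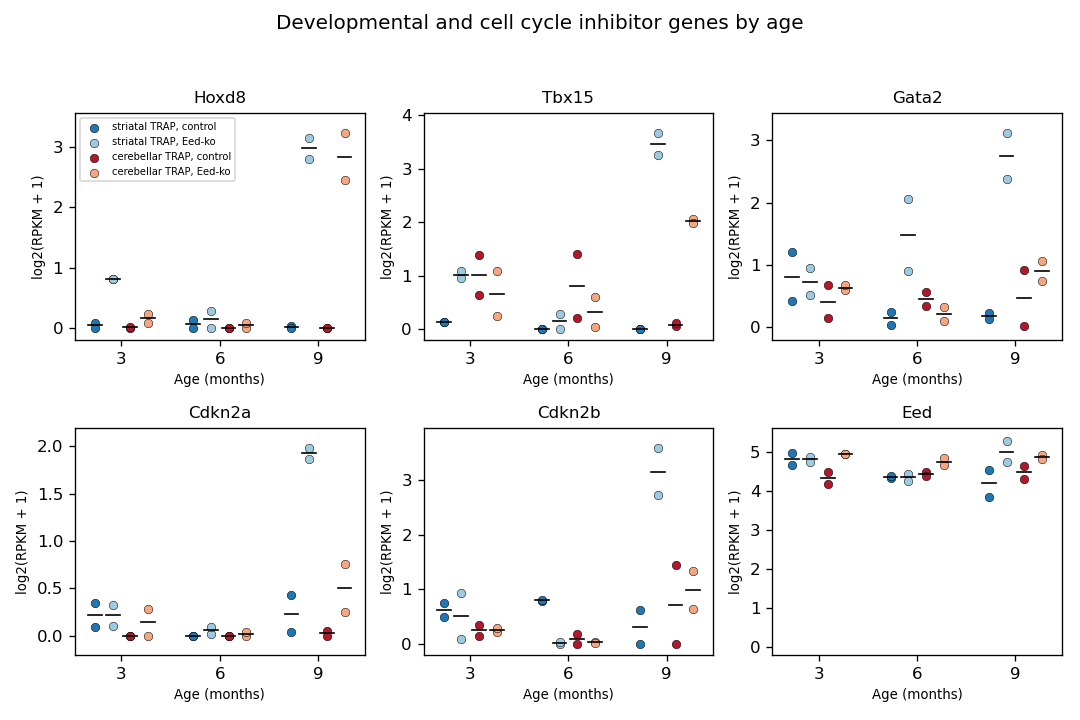
log2(RPKM + 1) of 3 developmental transcription factor genes, 2 cell cycle inhibitor genes and Eed in each TRAP library at 3, 6 and 9 months, coloured by region and genotype, with a bar at the mean of 2 libraries. Hoxd8 averaged 6.96 RPKM in striatal and 6.45 in cerebellar Eed-ko libraries at 9 months and stayed near 0 in controls.

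The age difference in control microglia was taken as 9 minus 3 months (n = 2 each). Y-linked transcripts and run format differ between these ages too, so no change below can be assigned to age alone. Y-linked genes fell, with Ddx3y at 16 ± 1.36 RPKM in striatum and 19.5 ± 5.84 in cerebellum at 3 months and near 0 at 9 months, and 4 of 5 sex-linked genes fell in both regions (camera adjusted p = 7.15e-12 and 9.65e-12, adjusted p = 0.00152 and adjusted p = 0.00159 with an estimated correlation). Cd9, a tetraspanin, fell from 275 ± 30.8 to 60.7 ± 15.5 RPKM in striatum and by -1.62 in cerebellum. The demethylase Kdm6b fell by -2.32 and -1.95 and its relative Kdm6a rose by 1.05 and 0.99. The myelin gene Cldn11 fell by -2.94 in striatum and -1.93 in cerebellum, with 3 and 4 of 14 oligodendrocyte genes down (5 in each adjusted over the list alone; camera adjusted p = 0.00541 and 0.00342, adjusted p = 0.466 and adjusted p = 0.824 with an estimated correlation). Fblim1, Prr12, Rai1, Fam100b and Jun rose in striatum by 2.09 to 1.63, and Hif3a, Cox4i2, Tmem160, Hint3 and Nradd in cerebellum by 2.31 to 1.97. Atp5l2 fell by -4.47 and -4.10, Rraga and Scarna9 fell in striatum by -2.37 and -2.54, and Nr4a2, Kalrn and Pbk in cerebellum by -2.76 to -2.49. Of 9 alternative settings, Atp5l2 kept its call in 9 in both regions and Rraga in 9 in striatum. Rai1 and Jun kept it in 3 and Scarna9 in 1 in striatum. In cerebellum, Kalrn kept it in 8, Cox4i2 in 3, Hif3a and Hint3 in 2 and Nradd in 1.

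In limma's test, 223 genes differed in striatum (56 higher, 167 lower) and 295 in cerebellum (85 higher, 210 lower). Rescaling to the TRAP-enriched genes brought the medians of all genes to -0.30 and -0.37 and gave 12 higher and 106 lower, and 17 and 184. In cerebellum, a fit of the 3- and 9-month controls alone called 26 genes (6 higher, 20 lower), voom 157 and the fit without the filter on low values 505. From 6 to 9 months, 9 genes differed in striatum (1 higher, 8 lower), Dync1h1 and Ryr2 among the lower at -1.73 and -1.43, and 11 in cerebellum (2 higher, 9 lower). The striatal count was 59 without 3-month control replicate 1, and 131 and 46 without 9-month control replicates 1 and 2. The cerebellar one was 135 and 63 without 3-month control replicates 1 and 2 and 171 without 9-month control replicate 1.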

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

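Tests chosen only after the result was seen were those of uniform dilution, of class II genes after rescaling, of border macrophages, of tissue or choroid plexus RNA against developmental genes and of sex or run, the carry-over covariate, and the comparison of enrichment between regions.

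In cerebellar against striatal control libraries 20 of 22 homeostatic genes were lower and 4 of 7 MHC class II and 8 of 12 border macrophage genes higher, amid 5971 genes that differed, but the class II list did not pass camera (adjusted p = 0.268) and the homeostatic and border lists lost their calls, with adjusted p = 0.292 and adjusted p = 0.711 with an estimated correlation. After rescaling to their own median, 599 of 1248 TRAP-enriched genes still differed, which argues against a single factor common to all of them. Dilution by tissue RNA lowers strongly enriched genes more than weakly enriched ones. It can therefore leave such differences, and the rescaling cannot decide on it. Before rescaling, dilution would lower genes that the capture enriched in cerebellum. All class II and border macrophage genes tested against cerebellum tissue were enriched there, so the 4 and 8 higher ones argue against dilution as their source. RNA of the surrounding tissue in the TRAP libraries stays open as a partial cause. Of the 5166 called genes that were not enriched, 79.5% differed in the same direction between the tissue RNAs of the regions. This lies between the bounds set for and against it. Of the 599 enriched genes 74.5% did, but that share cannot decide, since tissue RNA also holds microglial RNA. P2ry12, for instance, had 10.7 RPKM in striatum tissue and 2.77 in cerebellum tissue. Chance is argued against for the count as a whole, as 1 of 100 splits within age, the real one, reached 5971 genes and the next had 3160. The splits did not test the homeostatic, class II and border macrophage lists apart, so the count cannot decide on these. A regional difference of the microglia themselves, and a larger share of border macrophages in cerebellum, may remain and were not tested apart.

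MHC class II genes had a median of -1.46 in cerebellar Eed-ko libraries, with 2 of 7 lower over all genes tested and a list call that was lost at adjusted p = 0.116 with an estimated correlation. Dilution by tissue RNA is argued against by a median of -1.06 (standard error 0.27) after rescaling to the TRAP-enriched genes. After that rescaling the homeostatic list, which the capture strongly enriched, had a median of -0.09. An even loss of border macrophages as the only source would need their list to fall as far, but its median was -0.09 (SD over members 0.44). Loss of only a part of these cells was not tested. Without cerebellar 6-month control replicate 2, which had few border macrophage transcripts, that median was -0.61 (SD 0.51) beside -1.69 for class II, so a smaller loss of these cells could account for part of it. Of 100 splits within age, 1, the real one, gave a mean class II change as large in size (the next was 1.42 in size), and an effect of Eed loss stays open as a hypothesis, with the interaction at adjusted p = 0.758 with an estimated correlation.

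Developmental transcription factors, among them Hoxd8 and Tbx15, were higher in striatal Eed-ko libraries at 9 months, though with the carry-over score as a covariate limma called 0 genes (750 at an unadjusted p under 0.05), where the change of Tbx15 stayed at 3.52 and its standard error grew from 0.39 to 0.66. All 10 members that rose had a lower value in both striatal tissue libraries than in either Eed-ko library, which argues against RNA of control tissue. The choroid plexus list had a median of 1.29. Of the 10 members, 9 were lower in cerebellum tissue RNA, which held more choroid plexus RNA (Ttr at 938 and 1010 RPKM, against 328 and 2.9 in the Eed-ko libraries). This argues against choroid plexus RNA of controls for these 9, while it stays open for Otx2. Tissue RNA of Eed-ko animals was not measured, so these tests cannot decide on it. Depth is argued against as well, since 11 members rose after every library was thinned to 20.7 M reads, where 122 genes passed. Sex in place of age cannot be told apart, as all 8 of the 9-month TRAP libraries had Ddx3y under 1 RPKM and all 16 others were above it. The run format is argued against, since 6-month libraries share that of 9 months. The median of the developmental list in striatum was 0 at 6 months and 1.05 at 9 months. Whether these ages shared a run is not given, nor whether Eed-ko and control libraries did at 9 months. Loss of Polycomb repression in Eed-ko at this age stays open as a hypothesis that was not tested apart.

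Other splits were counted for the remaining comparisons, 100 of each within age. For the region difference in Eed-ko, 1 split, the real one, gave 6170 genes and the next 4451, which argues against chance for the count as a whole. For Eed loss in striatum, 2 splits gave 17 or more genes, the real one included. The other gave 177 by exchanging 3-month control replicate 1 with 3-month Eed-ko replicate 2, for a reason that was not tested. Since a wrong labelling gave more genes than the real one, the count does not exclude chance. For Eed loss in cerebellum, 5 splits gave 60 or more, so chance is not excluded, and 2 gave over 3 times as many, the highest 292 by exchanging replicate 2 of the 9-month control and Eed-ko groups. For the interaction limma called 0 genes, with 1380 at an unadjusted p under 0.05 and 0 by voom, so all 100 splits gave as many by construction and their count decides nothing (the highest other gave 11).

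The Eed effect differed between ages in 9 genes in striatal and 6 in cerebellar microglia by limma's F-test. TRAP enrichment over tissue differed between regions in 575 of 14186 genes, 331 more and 244 less enriched in cerebellum. The Eed effect differed between regions in 3 lists by camera, with adjusted p of 0.00105 for MHC class II, 0.00235 for neurons and 0.0316 for disease-associated microglia, and all 3 calls were lost, at adjusted p = 0.758, adjusted p = 0.793 and adjusted p = 0.793 with an estimated correlation.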

How the results depend on the processing

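Alternatives chosen only after the data were seen were voom, the carry-over covariate, leaving out an age, rescaling to the TRAP-enriched genes, and all alternatives of the comparison among enriched genes. The covariate was not applied to the region comparisons, whose groups do not overlap in it. Since it contains the homeostatic list, it can also absorb a change of these genes in the microglia themselves. Of 7391 values of named genes and list calls under alternatives, 6107 kept their direction and side of the threshold, 1245 lost the threshold, 11 gained it and 28 reversed. They include the 134 list calls, each repeated with an estimated correlation and on ranks. Region counts and TRAP enrichment counts moved by over 1.5 times only where given here. With an estimated correlation 126 of 134 list calls were lost and 8 stayed. Where a left-out library leaves a group with 1, that one is assumed to vary like the others. Fits of own groups change the libraries and the genes tested together. Depth limits genes under 1 RPKM.

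Given in the order striatal Eed loss, cerebellar Eed loss, then by age, no filter gave 75 and 108 genes, 47 for the interaction, 91 and 50 in striatum at 3 and 6 months, 99 for change with age, 164, 50 and 45 in cerebellum at 3, 6 and 9 months, 118 for change with age, and 505 for cerebellar age. A pseudocount of 0.1 gave 4 and 3 for change with age in striatum and cerebellum. Quantile normalization gave 4 for striatal Eed loss and 28 for cerebellum at 9 months. Voom gave 5 for cerebellar Eed loss, 12 and 205 in striatum at 6 and 9 months (72 shared with limma at 9), 32 and 162 in cerebellum, 0 and 0 for change with age, and 157 for cerebellar age. By library-name number, all 6 correlations between striatum and cerebellum were positive, 0.03 to 0.18, and by title number they were -0.18 to 0.10. Number 78 had the lowest Lyve1 among controls of each region, 0.123 RPKM in cerebellum and 0.764 in striatum. At 9 months, Xist in cerebellum and striatum was 8.4 and 7.74 RPKM in number 38 and 0.758 and 0.839 in number 48. In controls it was 1.1 and 1.3 in number 50 and 0.816 and 1.54 in number 52, not ordered alike. Shared animals stay possible, and the labels do not settle it. Blocks by title number gave 1 for striatal Eed loss, 0 and 39 in striatum at 6 and 9 months, 7, 10 and 11 in cerebellum at 3, 6 and 9 months, and 2 and 1 for change with age. Own groups only gave 4 and 0, then 0 and 0 in striatum at 6 and 9 months, 9, 0 and 0 in cerebellum, 2 and 2 for change with age and 26 for cerebellar age. The carry-over covariate gave 0 and 2, 0 and 0 in striatum at 6 and 9 months, 1 for striatal change with age and 4 in cerebellum at 6 months. Without 9-month libraries the counts were 2 and 112; without 3-month libraries 0 and 0, and 3674 for region in Eed-ko. Rescaling gave 9440 and 11108 for region in controls and Eed-ko and 881 for cerebellar Eed loss. Split controls took r from 0.29 to 0.16.

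Leaving out 1 library gave 5187 to 5972 for region, 3 to 124 and 1 to 376 for Eed loss, 0 to 1 for the interaction and 5272 to 6382 for region in Eed-ko. Striatum at 3, 6 and 9 months gave 2 to 29, 4 to 31 and 35 to 512, and 2 to 31 for change with age. Cerebellum gave 4 to 30, 19 to 61 and 33 to 247, and 5 to 34. Age gave 46 to 220 and 63 to 343, TRAP against tissue 4026 to 5116 and 1708 to 5084, and enriched genes 507 to 587.

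Reversals, as log2 changes: with quantile normalization B2m 0.05 in region in Eed-ko; with the covariate Cx3cr1 0.12 in cerebellar Eed loss and 0.18 in the interaction. Without 9 months, Eed -0.02 in striatal and Suz12 0.06 in cerebellar Eed loss; without 3 months, Eed 0.18 in region and -0.05 in the interaction. Rescaled, in region, Eed 0.63 (adjusted p = 0.00931), Tapbp 0.05, Xaf1 0.12, Ccnb1 0.17 and Mobp 0.18; in cerebellar Eed loss, Ezh2 0.27 and Suz12 0.31; in region in Eed-ko, H2-K1 0.14, B2m 0.14, Cdkn2a 0.32, Cdkn2b 0.03, Plac8 0.20, Mobp 0.23 and Cspg4 0.01. Eed in region ranged from -0.16 to 0.08 over single left-out libraries, with 0.08, 0.02, 0.01 and 0.01 without striatal 9-month control 1, cerebellar 9-month control 2, cerebellar 3-month control 2 and striatal 3-month control 2. Enriched genes without rescaling had Npc2 -0.29, H2-DMa -0.29 and Nfkbia -0.09.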

Other observations

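The capture separated some genes more in one region than in the other, a comparison chosen only after the data were seen, as was the look at single libraries here. H2-Aa, a class II chain, exceeded tissue RNA by a log2 change of 0.43 in striatum and 4.70 in cerebellum, a difference of 4.27. The scavenger receptor Cd163 and the complement receptor Vsig4 differed by 3.58 and 3.46 in the same direction. The transcription factor Maf, with 5.38 in striatum and 2.28 in cerebellum, and Ebf3 and Rps6ka1 were enriched less in cerebellum, by -3.10, -3.60 and -3.32. By list, the median difference was 2.34 for MHC class II (3 of 7 genes past the test, all higher), 2.14 for border macrophages (3 of 11) and -0.41 for homeostatic genes (2 of 22, both lower). Markers of other cells moved as well, with 1.96 for striatal neurons (7 of 15), which have little RNA in cerebellum to be depleted, 1.03 for astrocytes (1 of 12), 0.98 for oligodendrocytes (3 of 14) and 0.51 for neurons (3 of 16), and no list test was run on these differences.

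Cd74 in Eed-ko against control had log2 changes of -1.15, -2.23 and -2.69 at 3, 6 and 9 months in cerebellum and -0.12, -1.28 and 1.04 in striatum, none at adjusted p under 0.05 at a single age.

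The processed pseudogene Gm13394 stood at 24.5 to 27.3 RPKM in the 3-month controls of both regions and at no more than 0.281 in the other TRAP libraries. In tissue RNA it had 0.304 and 45.7 RPKM in striatum replicates 1 and 2, and 0.0774 and 26.2 in cerebellum replicates 1 and 2. Gm6430 had 11.3 and 11.5 RPKM in striatal and 4.29 and 5.07 in cerebellar 3-month controls, and 1.46 and 1.93 in tissue replicate 2 of striatum and cerebellum. Gm11987 had 6.12 and 2.99 RPKM in the cerebellar 3-month controls and was listed at 0 elsewhere. No explanation was tested.

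Ddx3y, on the Y chromosome, had 15 to 26.7 RPKM in 3-month, 10.8 to 17.2 in 6-month and 0 to 0.0995 in 9-month TRAP libraries. Xist had 0.00182 to 0.0478, 0 to 0.503 and 0.758 to 8.4 RPKM. The labels give no sex.

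Eed RPKM was not lower in libraries labelled Eed-ko. Which exons the floxed allele removes is not given in the sources used here, and a value per gene does not show a lost exon, so the level neither checks nor contradicts the labels. The names of the tissue columns differ, 1 per region marked as input and 1 as unbound.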
